A study of Mus musculus with 6 samples.

How the data were processed

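Total RNA from 6 samples of mouse cells, 2 each of HSC, ProT and DP, was hybridized to Affymetrix gene arrays after biotin labelling, per the labels' protocols. The values analysed were deposited as 1 table with a log2 signal for each of 35556 probe sets and 6 arrays, and per the submitters' processing notes they were made with RMA (background correction, normalization between arrays and a summary per probe set) and Partek. Versions and settings of RMA and Partek are not given in the sources used here. The deposited values lay between 3.22 and 14.38, the lower quartiles of the arrays between 5.26 and 5.41, the medians between 6.73 and 6.91, and the upper quartiles between 9.17 and 9.24. The scanner files were not used here.

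A table of the array's probe sets linked 21789 probe sets to exactly 1 gene, and these covered 19938 genes. For the 999 genes with more than 1 probe set, the probe set with the highest mean over the 6 arrays stood for the gene. The 1621 probe sets with several genes and the 12146 with no gene listed were left out of the gene-level tests, and probe sets named as controls and spike-ins were not analysed here. Gene names were matched to the reference table by gene identifier for 21698 probe sets, with 0 names changed. No filter on signal was applied and no genome coordinates were used.

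All 6 arrays were fitted in 1 linear model per gene with a mean for each population in limma 3.58.1 under R 4.3.3, followed by eBayes with a constant prior (residual degrees of freedom 3, prior degrees of freedom 2.83). The comparisons were ProT against HSC, DP against ProT, DP against HSC, and ProT against the midpoint of HSC and DP. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all 19938 genes of a comparison, with no minimum change, and the standard errors are the moderated ones. A gene was counted as highest or lowest in ProT when both steps were called in opposite directions. The simulations of unchanged groups planned for the number expected by chance give 0 because of the threshold alone and were not used. A gene was counted as early or late when the HSC to DP difference and the midpoint contrast were both called, with ProT on the DP or the HSC side of the midpoint. A gene highest or lowest in ProT could be counted as early or late as well. The replicate numbers of the labels were not used in the main fit.

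Gene groups were tested as 26 lists written from general knowledge before the values were seen, with 517 members of which 473 were measured (1 under a synonym). The other members are not analysed here. Some genes belong to more than 1 list, so the results of the lists are not independent of each other. Each list was tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over the 78 tests of all lists and 3 comparisons, and beside it with the correlation estimated from the data and with fry. With the estimated correlation, camera also takes its p-value from the 3 residual degrees of freedom of the fit, far fewer than with the preset. The 2 p-values of a list can thus differ through more than the correlation. Members called when adjusted over the list alone were counted as well. Genes named in the comparisons followed a rule set before the data were examined. The rule takes, for each comparison, the 8 largest rises and 8 largest falls among called genes whose groups do not overlap and whose higher mean reaches the median of all gene values (7.17), passing over genes without a proper symbol. It adds for each list up to 4 called members and up to 2 members that did not pass, by size of change, a fixed set of 22 stage genes, and the 5 genes furthest above and below the midpoint among those highest or lowest in ProT.

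The scripts were tested on simulated data with the array layout of ProT against HSC: of 50 changed genes at each size, 36%, 94.0%, 100% and 100% were called at log2 changes of 0.5, 1, 2 and 4, and 10 of the 175 calls (5.71%) were among unchanged genes. Of 50 lists of unchanged genes 0 were called. The simulated genes varied independently, so this does not measure false calls among lists of correlated genes. Alternatives were a replicate block, quantile normalization, median centring, a filter on dim genes (at or above the median of all values in at least 2 arrays), the mean or the most variable probe set per gene, all probe sets, a trended robust prior, fits of only the populations compared, stricter thresholds, leaving out each array, other list tests and other correlations, and cyclic loess. For the closing section, second lists of marker genes for thymic epithelium, fibroblasts, endothelium, macrophages, B cells, mast cells and NK cells, and comparison lists for liver, muscle and neurons, were compared with 10000 random lists matched on mean signal. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 prepared the tables.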

Results

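Gene expression was profiled on 6 Affymetrix arrays of mouse cells taken at 3 points on the way from blood progenitors to thymocytes, with 2 arrays for each population. The HSC samples were bone marrow cells carrying the fusion protein NUP98-HOXB4, which lets blood progenitors expand in culture, grown with the cytokines IL6 and SCF. The ProT samples were such cells after culture with DLL4, a ligand of the Notch1 receptor, and IL7, a cytokine that lymphoid progenitors depend on. The DP samples were double positive thymocytes, the stage that carries both CD4 and CD8, which arose from ProT cells after their transfer into mice lacking Rag2. Signals are log2 values for 19938 genes, and the array medians over all probe sets lay between 6.73 and 6.91. Across all probe sets, the replicate arrays had a Pearson correlation of 0.991 for HSC, 0.995 for ProT and 0.997 for DP. Between populations the mean correlation was 0.968 for HSC and ProT, 0.947 for ProT and DP, and 0.936 for HSC and DP, so each pair of replicates was closer than any pair of populations. The replicate arrays differed at least 2-fold at 204 genes in HSC, 144 in ProT and 0 in DP. The number of arrays limits the precision, and since the labels do not say that replicates came from separate cultures or animals, the p-values measure the spread between these samples, which may be technical.

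The study's question was how gene activity changes between multipotent progenitors, T-committed cells and their double positive descendants. limma with Benjamini-Hochberg adjustment called 2940 genes between ProT and HSC, 6506 between DP and ProT and 6953 between DP and HSC. Group means are given on the log2 scale with their SD over 2 arrays, and changes as log2 fold changes with their standard errors from limma. A fold is given as at least its measured size where the lower mean lay below 7.17, the median of all gene values, since such signals were not shown to lie above background. Log2 changes are differences of measured signal, and those that involve such means carry the same limit.

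ProT cells differed from HSC by higher genes of the T cell, NK, and dendritic cell and MHC class II lists and by lower granulocyte and monocyte genes. Cd3g, a chain of the T cell receptor complex, rose at least 293-fold, from 4.83 ± 0.12 to 13.02 ± 0.04 (adjusted p = 1.11e-06), and its partner Cd3e rose at least 66.6-fold. Cd7, an early lymphoid surface protein, rose at least 128-fold, Il2ra, the interleukin 2 receptor chain that marks early thymocytes, at least 106-fold, and the gamma chain segment Trgv1 at least 194-fold. The cytotoxic proteases Gzmb and Gzma rose at least 233-fold and at least 201-fold, and the mast cell proteases Mcpt1 and Mcpt2 rose at least 193-fold and at least 84.7-fold. Among the large falls, Ly6a2, of the Ly6 surface protein family, fell at least 127-fold, the acute phase gene Saa3 at least 112-fold, F13a1, a coagulation factor subunit made by monocytes, at least 72.4-fold and Ms4a3, of granulocyte progenitors, at least 69.7-fold. In all, 1565 genes were higher and 1375 lower in ProT, of which 692 and 538 changed at least 2-fold.

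Genes that Notch signalling switches on rose as a group, with 9 of 12 measured members higher and 0 lower (10 and 0 when adjusted over the list alone). Hes1, a repressor induced directly by Notch, went from 5.80 ± 0.20 to 9.66 ± 0.17, a log2 change of 3.86 ± 0.14. Dtx1, a regulator of the pathway, changed by 3.85 ± 0.12, Nrarp, its feedback inhibitor, by 2.20 ± 0.22, and the receptor gene Notch1 itself by 1.36 ± 0.08. Heyl did not pass the test, at 1.11 ± 0.38. The camera test on the list gave an adjusted p = 6.05e-11, and an adjusted p = 0.0709 with an estimated correlation. Of the list of T lineage transcription factors, 12 of 18 rose and 1 fell (12 and 3 when adjusted over the list alone). Gata3, needed for T cell specification, changed by 5.87 ± 0.08, Tox by 3.74 ± 0.08 and Ikzf3 by 2.33 ± 0.08, and Bcl11b, the factor of T cell commitment, rose by 1.25 ± 0.08 to 8.40 ± 0.05. Camera gave an adjusted p = 3.23e-07 for these factors, and an adjusted p = 0.143 with an estimated correlation. The list of the T cell receptor complex and its signalling had 17 of 21 members higher and 0 lower (18 and 0 when adjusted over the list alone), among them Rasgrp1 (5.09 ± 0.31) and Themis (4.47 ± 0.40). Its camera adjusted p was 1.68e-17 and stayed past the threshold with an estimated correlation (adjusted p = 0.046), the only list to do so in this comparison.

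Genes of later thymocytes were split at this step. Of the double positive thymocyte list, 11 of 20 members rose and 0 fell (11 and 4 when adjusted over the list alone). The list had a camera adjusted p = 1.37e-05, and an adjusted p = 0.114 with an estimated correlation. Ccr9, a thymus homing receptor, rose by 5.85 ± 0.13, while the co-receptor genes Cd4 (0.16 ± 0.08) and Cd8a (0.10 ± 0.07) did not pass. Rag1, which cuts receptor genes during V(D)J recombination, rose by 1.09 ± 0.15 and its partner Rag2 did not pass (0.57 ± 0.30). The V(D)J recombination list as a whole had 3 of 11 members higher and 0 lower (4 and 0 when adjusted over the list alone) and was not called by camera (adjusted p = 0.0879). Ptcra, the pre-T cell receptor alpha chain, rose by 1.74 ± 0.11. Of the mature T cell list, 12 of 18 rose and 1 fell (12 and 1 when adjusted over the list alone). Its largest rises were those of Il7r, the IL7 receptor, at 5.17 ± 0.17, the chemokine receptor Ccr4 at 3.99 ± 0.09 and the co-stimulatory receptor Icos at 3.68 ± 0.16. Camera gave an adjusted p = 7.08e-10 for that list, and an adjusted p = 0.0804 with an estimated correlation. Cytokine receptor and STAT target genes went both ways, 9 up and 4 down of 17 (12 and 4 when adjusted over the list alone), with the STAT5 targets Socs2 (4.77 ± 0.16) and Cish (2.55 ± 0.20) among the rises. The list's camera adjusted p was 7.74e-05, with an adjusted p = 0.173 with an estimated correlation.

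Myeloid genes fell almost throughout, 25 of 29 lower against 2 higher (26 and 2 when adjusted over the list alone), with a median log2 change of -2.31. Csf3r, the G-CSF receptor, changed by -4.98 ± 0.12, the neutrophil granule genes Ngp and Prtn3 by -4.84 ± 0.68 and -4.83 ± 0.34, and Spi1, which encodes the myeloid and progenitor factor PU.1, by -1.01 ± 0.22, to a mean that was still 11.30 ± 0.34. Camera gave an adjusted p = 5.98e-19, and an adjusted p = 0.22 with an estimated correlation. Stem and progenitor genes moved less, 3 up and 7 down of 24 (5 and 7 when adjusted over the list alone), and the list was not called by camera (adjusted p = 0.219). Mecom and Lmo2, regulators of stem cell programs, changed by -2.74 ± 0.30 and -2.42 ± 0.09, Mycn by 3.71 ± 0.38, and Kit, the SCF receptor, by 0.72 ± 0.10. Gata2 (-0.87 ± 0.37) and Meis1 (0.26 ± 0.22) did not pass. Of the Hox genes and cofactors, 5 of 18 fell and 0 rose (7 and 0 when adjusted over the list alone). Those that fell include Hoxb2 (-1.14 ± 0.16), Hoxb4 (-1.06 ± 0.22), Hoxb5 (-0.93 ± 0.12) and Hoxb3 (-0.72 ± 0.08), while Hoxa9 did not pass at -0.28 ± 0.08. Whether the Hoxb4 signal includes transcript of the NUP98-HOXB4 fusion was not tested. The Hox list had a camera adjusted p = 0.000141, and an adjusted p = 0.285 with an estimated correlation.

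Genes of the NK list and of the dendritic cell and MHC class II list rose in ProT together with the T cell genes, and mast cell genes went both ways. Of the NK and innate lymphoid list, 13 of 20 rose and 0 fell (14 and 0 when adjusted over the list alone). Among them were Gzmb, Gzma, the interleukin 2 receptor chain Il2rb (5.92 ± 0.21) and the chemokine Xcl1 (4.04 ± 0.32). Nkg7 (0.18 ± 0.09) and Eomes (0.45 ± 0.11) did not pass. Camera gave an adjusted p = 2.58e-13 for this list, and an adjusted p = 0.104 with an estimated correlation. In the mast cell and basophil list 5 of 12 rose and 2 fell (5 and 3 when adjusted over the list alone), and the list was not called by camera (adjusted p = 0.11). Mcpt4 changed by 6.33 ± 0.10 and the IgE receptor chain Fcer1a by 4.49 ± 0.09, but Hdc, the histamine-forming enzyme, by -3.03 ± 0.19. The dendritic cell and MHC class II list had 7 of 15 members higher and 1 lower (8 and 1 when adjusted over the list alone). The members that rose most were antigen presentation genes, H2-Aa (5.57 ± 0.17), Cd74 (4.24 ± 0.25) and H2-Ab1 (3.72 ± 0.52). Its camera adjusted p was 0.000108, and its adjusted p = 0.173 with an estimated correlation. Immediate early and heat shock genes, which respond to handling and stress, also rose, 8 of 16 with 1 lower (9 and 3 when adjusted over the list alone). Egr1 (2.52 ± 0.33) and Nr4a1 (1.86 ± 0.11), which T cell receptor signals induce as well, were among them. Camera gave them an adjusted p = 0.000408, and an adjusted p = 0.28 with an estimated correlation. The cell cycle list had 2 of 27 members lower, Aurkb (-0.46 ± 0.11) and Mcm5 (-0.28 ± 0.07), and 0 higher (0 and 0 when adjusted over the list alone). It had a camera adjusted p = 0.000191 and an adjusted p = 0.346 with an estimated correlation. For B lineage genes 4 of 17 rose and 1 fell, for macrophage genes 3 of 14 and 2, for stromal and thymic epithelial genes 3 of 20 and 1, and for erythroid and megakaryocyte genes 2 of 15 and 2. Camera called none of these 4 lists (adjusted p = 0.315, 0.542, 0.466 and 0.716). Also not called by camera were glycolysis (1 of 12 higher, 0 lower, adjusted p = 0.221) and ribosome biogenesis (0 of 23 higher, 0 lower, adjusted p = 0.454). The same holds for the BCL2 family (4 of 11 higher, 0 lower, adjusted p = 0.312) and the type I interferon response (2 of 16 higher, 4 lower, adjusted p = 0.791). Adjusted over the list alone, the higher and lower counts of these 8 lists in the same order were 4 and 1, 3 and 3, 4 and 1, 2 and 2, 1 and 0, 0 and 0, 4 and 1, 3 and 4. The median, the mean and the test did not share 1 sign for the erythroid, B lineage, macrophage, stromal and interferon lists. fry asks whether members moved 1 way on average, without setting them against other genes. It passed for V(D)J recombination (adjusted p = 0.0278), mast cell (0.000508), B lineage (0.00531), stromal (0.0154) and BCL2 genes (0.0121). Without either of the DP arrays, when the DP group adds nothing to the variance estimate, 1013 genes were higher and 779 lower in ProT than HSC, and without ProT replicate 1 the count of lower genes was 854. Centring each array on its median moved the median of all genes to -0.09 and the share of higher genes among the calls from 53.2% to 42.0%, with 1321 genes higher and 1821 lower. Over probe sets linked to 1 gene, the array medians were 7.2248 and 7.192 in HSC and 7.2731 and 7.285 in ProT, so centring lowers ProT against HSC. Why these medians differ was not tested.

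**Figure D1:**
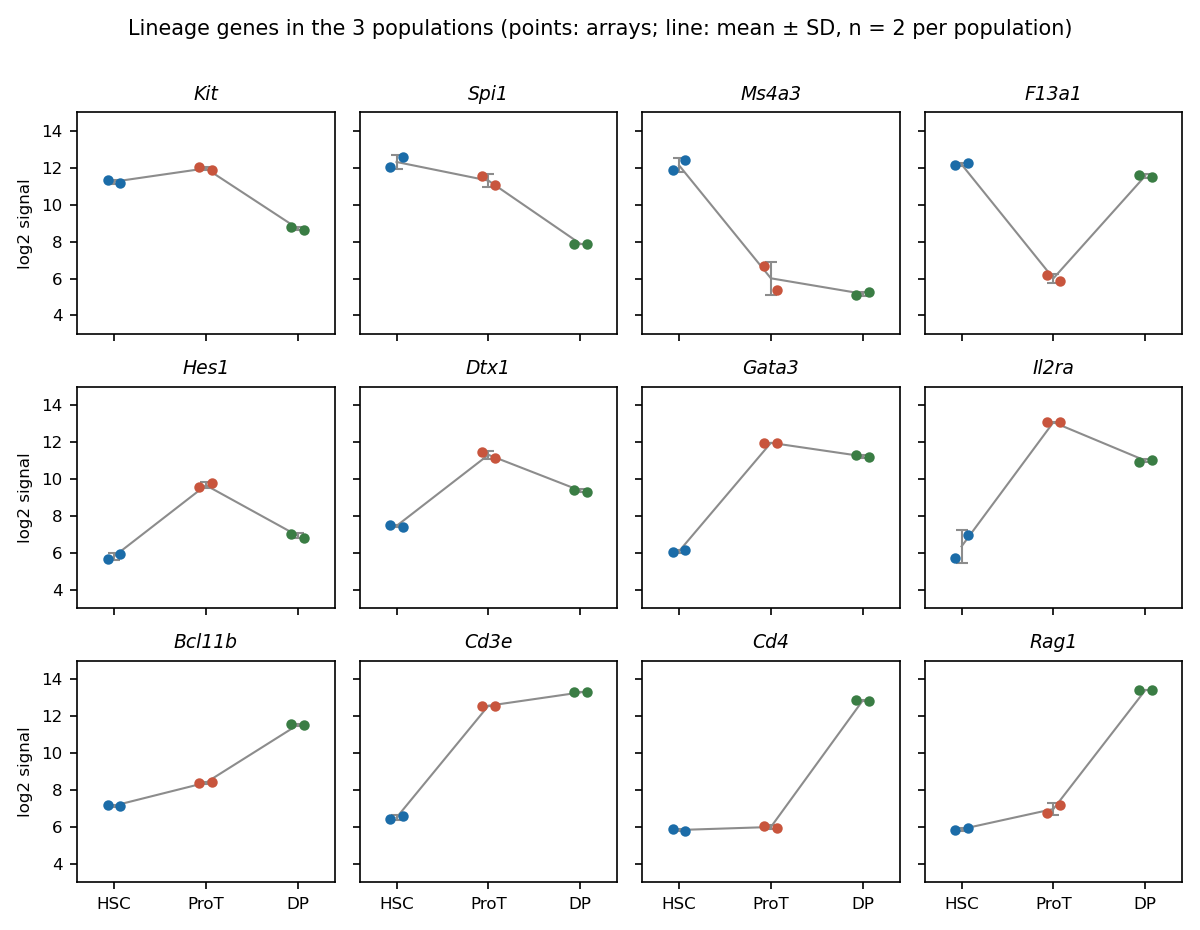
log2 signal (vertical axes) of 12 lineage genes in HSC, ProT and DP, with a point per array and a line through the means with SD bars (n = 2). Cd3e reached 12.57 already in ProT, Cd4 and Rag1 reached 12.86 and 13.41 in DP, and Hes1 was highest in ProT.

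The DP cells that had formed in mice differed from ProT by the full set of double positive thymocyte genes and by lower growth and energy metabolism genes. Dntt, the polymerase that adds nucleotides to receptor gene joints, rose at least 158-fold, from 5.45 ± 0.03 to 12.75 ± 0.00 (adjusted p = 1.57e-06). The co-receptor genes Cd4, Cd8b1 and Cd8a rose at least 116-fold, at least 94.4-fold and at least 94.2-fold, and Rag1 and Rag2 at least 86.5-fold and at least 28.5-fold. Sh2d1a, an adaptor of lymphocyte receptors, rose at least 62.1-fold and the adhesion receptor Cd2 at least 50.2-fold. Large falls were those of Mcpt1 (at least 213-fold) and Gzmb (at least 179-fold), and of Mcpt4 (at least 77.6-fold), Mcpt2 (at least 74.7-fold), the actin-severing gene Scin (at least 61.3-fold) and Cyp11a1, which starts steroid hormone synthesis (at least 56.0-fold). In this comparison 2899 genes were higher and 3607 lower in DP, with 879 and 1420 of them changed at least 2-fold.

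All 20 measured members of the double positive thymocyte list rose (20 when adjusted over the list alone), by a median log2 change of 3.87. The camera adjusted p was 5.44e-19, and this was the only list of the comparison still past the threshold with an estimated correlation (adjusted p = 0.046). For the T cell receptor complex and signalling, 20 of 21 members rose and 0 fell (21 and 0 when adjusted over the list alone), including Cd6 (4.63 ± 0.12) and Cd5 (4.01 ± 0.11). This list had a camera adjusted p = 2.32e-13, and an adjusted p = 0.0556 with an estimated correlation. Cd3g, already high in ProT, did not pass at 0.24 ± 0.09. Of the V(D)J recombination list 8 of 11 rose and 1 fell (8 and 1 when adjusted over the list alone), and the end-joining ligase gene Lig4 rose 8.01-fold. Camera gave an adjusted p = 6.55e-05, and an adjusted p = 0.277 with an estimated correlation. The double positive list shares Rag1 and Rag2 with the V(D)J recombination list, and Themis and Cd5 with the T cell receptor list. T lineage transcription factors rose in 12 of 18 cases and fell in 2 (13 and 2 when adjusted over the list alone). Their camera adjusted p was 6.02e-05, with an adjusted p = 0.173 with an estimated correlation. Lef1 changed by 5.11 ± 0.14, Ets1 by 3.63 ± 0.10 and Bcl11b by 3.13 ± 0.08, while Gata3 fell by 0.73 on the log2 scale. Mature T cell genes went both ways, 8 up and 4 down of 18 (9 and 4 when adjusted over the list alone), and were not called by camera (adjusted p = 0.334). Among them Cd40lg changed by 2.76 ± 0.16, Ccr7 by 2.15 ± 0.10 and Ctla4 by -2.22 ± 0.13.

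Notch target genes came down from their level in ProT, 7 of 12 lower and 1 higher (8 and 1 when adjusted over the list alone). Nrarp changed by -3.16 ± 0.22, Hes1 by -2.74 ± 0.14, Hey1 by -2.05 ± 0.27, Dtx1 by -1.94 ± 0.12 and Il2ra by -2.08 ± 0.38, whereas Ptcra rose by 0.73 ± 0.11. Notch1 itself did not pass (-0.03 ± 0.08, with a positive sign after quantile normalization, median centring or cyclic loess). Camera gave an adjusted p = 0.00256 for the list, and an adjusted p = 0.173 with an estimated correlation. Stem and progenitor genes fell in 17 of 24 cases and rose in 3 (17 and 4 when adjusted over the list alone). For them the camera adjusted p was 1.15e-06, and adjusted p = 0.274 with an estimated correlation. Cd34 changed by -4.22 ± 0.10, Bcl11a by -3.52 ± 0.12, Mycn by -3.92 ± 0.38, Kit by -3.26 ± 0.10, Gata2 by -2.96 ± 0.37 and Meis1 by -1.95 ± 0.22. The largest rise of the list was that of Slamf1 (4.23 ± 0.23), a surface receptor that thymocytes also carry. Among Hox genes and cofactors 5 of 18 rose and 3 fell (5 and 5 when adjusted over the list alone; camera adjusted p = 0.586), with Hoxa5 at 1.04 ± 0.07 and Hoxa9 not past the test at -0.24 ± 0.08. Of the myeloid genes 11 of 29 fell and 6 rose (12 and 8 when adjusted over the list alone). The camera adjusted p was 0.01 here, and adjusted p = 0.617 with an estimated correlation. Ctsg, a neutrophil protease, changed by -4.13 ± 0.10, Csf2rb, the shared chain of cytokine receptors such as that of GM-CSF, by -3.66 ± 0.20, and Spi1 by -3.42 ± 0.22. The NK list fell in 15 of 20 cases with 1 higher (15 and 2 when adjusted over the list alone), and the mast cell list in 9 of 12 with 0 higher (9 and 0 when adjusted over the list alone). These 2 lists had camera adjusted p values of 2.99e-07 and 7.43e-06, and adjusted p = 0.148 and 0.112 with an estimated correlation. Gzma kept a signal of 9.70 ± 0.11 in DP, 10.4-fold below ProT.

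Growth and metabolism genes were lower in DP. Of the genes of ribosome biogenesis and MYC targets 21 of 23 fell and 1 rose (22 and 1 when adjusted over the list alone), among them Odc1, of polyamine synthesis (-1.86 ± 0.18), and Polr1b, of RNA polymerase I (-1.66 ± 0.22). Of the glycolysis and glucose uptake genes 11 of 12 fell and 0 rose (11 and 0 when adjusted over the list alone), with Hk2, which phosphorylates glucose, at -3.46 ± 0.17 and the glucose transporter Slc2a3 at -3.13 ± 0.42. Cell cycle genes fell in 15 of 27 cases and rose in 0 (18 and 1 when adjusted over the list alone), such as Mcm3 (-1.36 ± 0.10) and E2f1 (-1.21 ± 0.16), while Mki67 did not pass (0.87 ± 0.40). Camera gave adjusted p values of 9.78e-09, 2.07e-07 and 4.42e-05 for these 3 lists, and adjusted p = 0.266, 0.263 and 0.3 with an estimated correlation. Cytokine receptor and STAT target genes fell in 10 of 17 cases and rose in 4 (10 and 4 when adjusted over the list alone). This gave a camera adjusted p = 0.00336, and an adjusted p = 0.251 with an estimated correlation. Socs2 changed by -4.92 ± 0.16 and Cish by -2.80 ± 0.20, while Il7r did not pass (-0.36 ± 0.17). The BCL2 family was not called by camera (3 of 11 higher, 3 lower, adjusted p = 0.791; 3 and 3 when adjusted over the list alone), with the survival gene Bcl2l1 at 2.21 ± 0.09 and Bcl2 at -1.52 ± 0.14.

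Markers of thymic stroma and B cells from the lists rose in DP beside the thymocyte genes, and macrophage markers went both ways. Of the stromal and thymic epithelial list 13 of 20 rose and 3 fell (14 and 3 when adjusted over the list alone). The stromal list had a camera adjusted p = 7.15e-05, and an adjusted p = 0.28 with an estimated correlation. Ccl25, the chemokine that thymic epithelium secretes, went from 7.21 ± 0.20 to 10.84 ± 0.06, and Dcn, a matrix protein of fibroblasts, from 4.90 ± 0.08 to 7.67 ± 0.01. In contrast, Epcam and Pdgfrb, at 10.02 and 11.62 in ProT, changed by -2.60 ± 0.09 and -3.62 ± 0.28. Macrophage genes rose in 7 of 14 cases and fell in 4 (7 and 4 when adjusted over the list alone) and were not called by camera (adjusted p = 0.164). The complement genes C1qb and C1qc changed by 3.13 ± 0.21 and 2.31 ± 0.08 and Adgre1, the F4/80 antigen, by -3.98 ± 0.31. B lineage genes rose in 11 of 17 cases and fell in 1 (12 and 1 when adjusted over the list alone). Among them were Rag1, which is not specific to B cells, Cd79a (1.93 ± 0.10) and Ms4a1 (1.80 ± 0.07), and the list had a camera adjusted p = 0.00055, and an adjusted p = 0.148 with an estimated correlation. The type I interferon list had 6 of 16 members higher and 2 lower (7 and 3 when adjusted over the list alone; camera adjusted p = 0.206), led by Ifit1 (3.10 ± 0.19). Also not called by camera were erythroid and megakaryocyte genes (1 of 15 higher, 4 lower, adjusted p = 0.16), dendritic cell and MHC class II genes (3 of 15 higher, 4 lower, adjusted p = 0.454) and immediate early genes (2 of 16 higher, 5 lower, adjusted p = 0.312). Adjusted over the list alone, their higher and lower counts were 1 and 4, 3 and 5, 3 and 5. Among lists that camera did not call, fry passed for mature T cell (adjusted p = 0.0294), macrophage (0.0102), BCL2 (0.0127) and interferon genes (0.0306). The median, the mean and the test did not share 1 sign for the Hox, BCL2 and DNA methylation lists. Without DP replicate 1 the counts were 1467 genes higher and 2280 lower, and without DP replicate 2 they were 1484 and 2047. Quantile normalization gave 3629 genes higher and 3044 lower, 54.4% higher against 44.6% in the values as deposited and 47.2% after cyclic loess. Centring each array on its median moved the median of all genes to 0.13 and gave 4522 genes higher and 2987 lower, so that 60.2% of the calls were higher. Over probe sets linked to 1 gene, the array medians were 7.2731 and 7.285 in ProT and 7.1495 and 7.1635 in DP, so centring raises DP against ProT. Why these medians differ, and why quantile normalization changed the balance, was not tested.

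**Figure D2:**
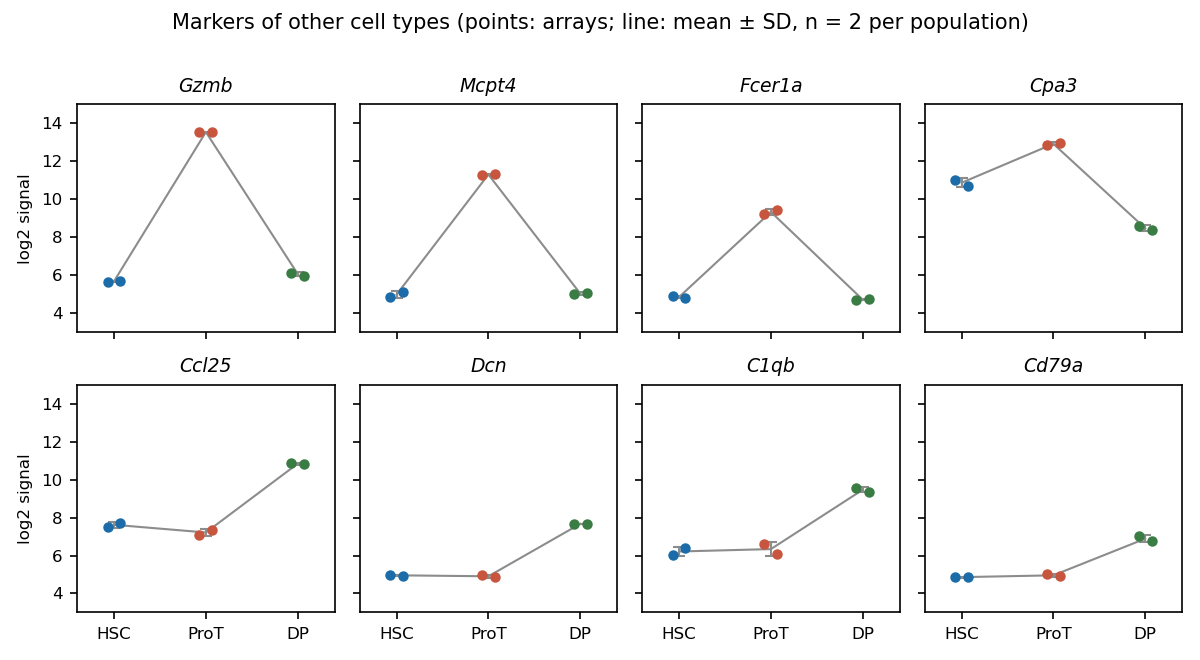
log2 signal (vertical axes) of 8 markers of NK, mast, thymic stromal, macrophage and B cells in HSC, ProT and DP, with a point per array and a line through the means with SD bars (n = 2). Gzmb, Mcpt4 and Fcer1a were at 4.70 to 6.05 outside ProT and at 9.33 to 13.54 in ProT, while Ccl25, Dcn, C1qb and Cd79a were highest in DP.

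Over the whole path from HSC to DP, 3195 genes were higher and 3758 lower, 1021 and 1727 of them at least 2-fold. All 21 measured genes of the T cell receptor list and all 20 of the double positive thymocyte list rose (21 and 20 when adjusted over each list alone), by medians of 5.10 and 5.29 on the log2 scale. These were the 2 lists past the threshold with an estimated correlation (adjusted p = 0.046 for both; camera adjusted p = 5.98e-19 and 5.44e-19). Ccr9 rose at least 204-fold and Themis, a regulator of thymocyte selection, at least 199-fold. Of the myeloid genes 28 of 29 fell and 0 rose (28 and 0 when adjusted over the list alone). Camera adjusted p was 5.98e-19 for them, and adjusted p = 0.22 with an estimated correlation. Ms4a3 fell at least 125-fold, Prtn3 at least 76.7-fold and Ctsg at least 68.8-fold. The C-type lectin receptor Clec4e fell at least 114-fold, and Spi1 changed by -4.43 ± 0.22 and Hoxb4 by -1.77 ± 0.22. Other lists called higher in DP than HSC were T lineage transcription factors (14 of 18 higher, 2 lower, adjusted p = 7.16e-08), mature T cell genes (14 of 18 higher, 1 lower, 2.14e-07), stromal and thymic epithelial genes (15 of 20 higher, 0 lower, 3.23e-07) and V(D)J recombination (9 of 11 higher, 0 lower, 1.25e-05). So were B lineage genes (13 of 17 higher, 0 lower, 1.31e-05), Notch targets (7 of 12 higher, 2 lower, 0.00206) and dendritic cell and MHC class II genes (10 of 15 higher, 2 lower, 0.0051). In the same order their adjusted p values with an estimated correlation were 0.132, 0.104, 0.251, 0.266, 0.112, 0.173 and 0.256. Their higher and lower counts adjusted over the list alone were 15 and 2, 14 and 1, 16 and 0, 9 and 1, 14 and 1, 7 and 2, 10 and 2. Lists called lower were cell cycle (21 of 27 lower, 0 higher, adjusted p = 4.26e-08), ribosome biogenesis (21 of 23 lower, 1 higher, 1.32e-08), stem and progenitor genes (17 of 24 lower, 2 higher, 3.23e-07), glycolysis (10 of 12 lower, 0 higher, 4.11e-06) and mast cell genes (6 of 12 lower, 0 higher, 0.00577). In that order these had adjusted p = 0.256, 0.266, 0.266, 0.274 and 0.189 with an estimated correlation. For these, 21, 22, 17, 10 and 6 members fell and 0, 1, 3, 0 and 0 rose when adjusted over the list alone. Camera did not call the Hox list (2 of 18 higher, 6 lower, adjusted p = 0.175), NK genes (9 of 20 higher, 4 lower, 0.0646), macrophage genes (6 of 14 higher, 3 lower, 0.204) and erythroid genes (1 of 15 higher, 6 lower, 0.164). Nor did it call cytokine and STAT genes (6 of 17 higher, 9 lower, 0.318), the BCL2 family (5 of 11 higher, 4 lower, 0.423), interferon genes (7 of 16 higher, 4 lower, 0.204) and immediate early genes (5 of 16 higher, 4 lower, 0.413). Of these, fry passed for the Hox list (adjusted p = 0.0229), NK (0.0186), macrophage (0.0116) and BCL2 genes (0.00209). The counts of all 8 adjusted over the list alone were 3 and 6, 11 and 4, 6 and 3, 1 and 6, 6 and 9, 5 and 4, 10 and 5, 6 and 4, and the median, the mean and the test of the cytokine list did not share 1 sign. Without DP replicate 1 the count of higher genes was 1982, and without DP replicate 2 the counts were 1940 higher and 2361 lower. Of the calls 46.0% were higher in the values as deposited, 49.6% after median centring, 48.2% after cyclic loess and 53.8% after quantile normalization (3856 higher and 3305 lower), the only scaling with more genes higher than lower; the causes were not tested.

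**Figure D3:**
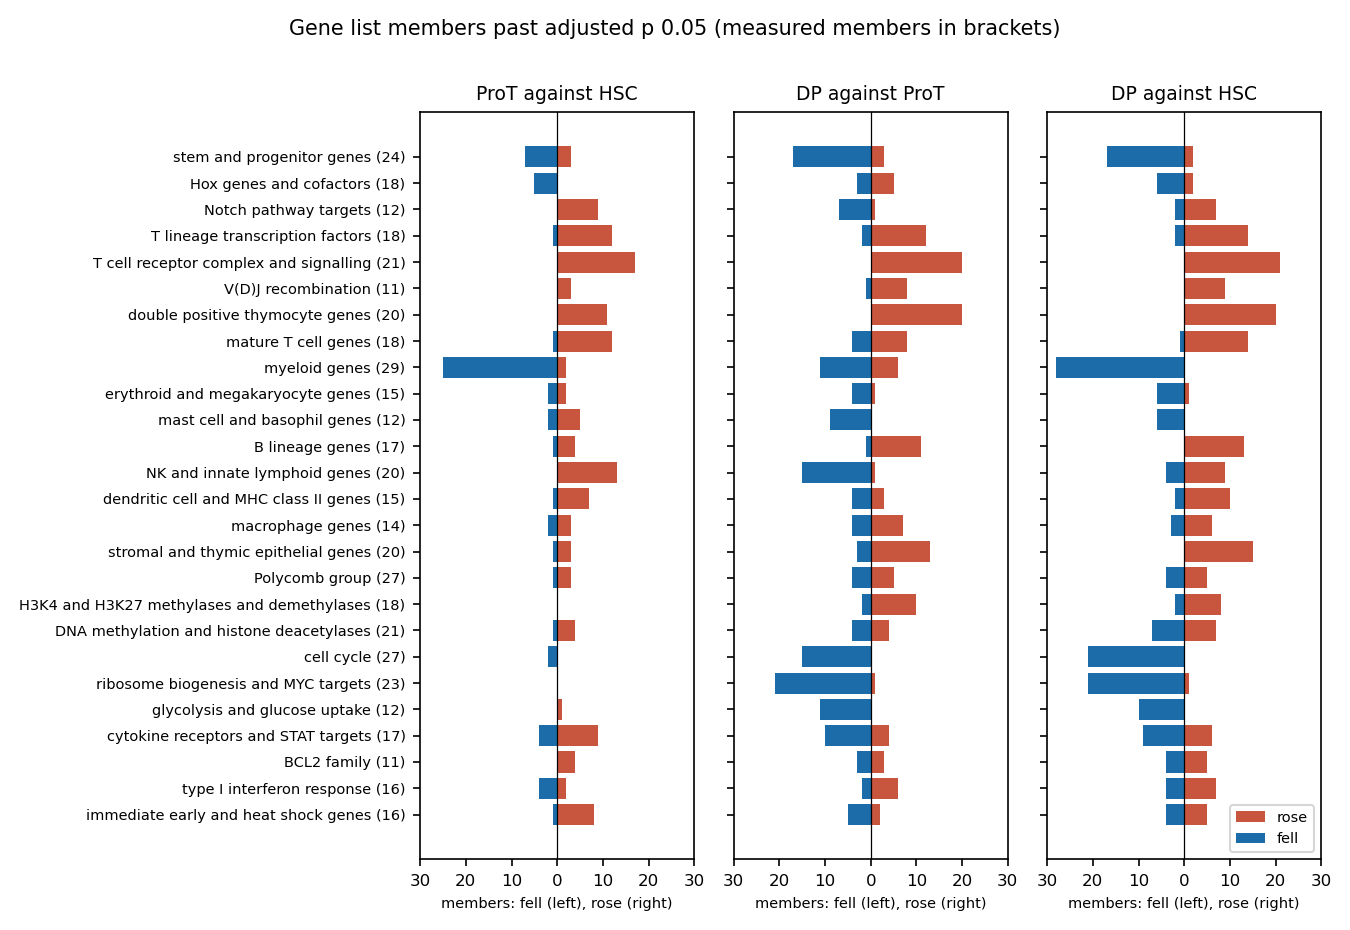
Number of members (horizontal axes) of 26 gene lists that rose or fell past an adjusted p of 0.05 in the 3 comparisons, with the measured members of each list in brackets. Double positive thymocyte genes rose in 11 of 20 cases in ProT against HSC and in 20 in DP against ProT, and myeloid genes fell in 25 of 29 cases at the earlier step.

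Of the 3 lists of chromatin regulators, the enzymes and complexes that set DNA and histone marks, 1 was called, and only by 1 of 2 kinds of test. Camera, which sets a list against all other genes, called none of them. fry called the H3K4 and H3K27 list in DP against ProT (adjusted p = 0.0108) and in DP against HSC (adjusted p = 0.00498), but not in ProT against HSC (adjusted p = 0.15). Its adjusted p values for the 3 comparisons were 0.738, 0.184 and 0.229 for the Polycomb group and 0.964, 0.704 and 0.756 for the DNA methylation list. The Polycomb group, which deposits and reads repressive histone marks, had 3 of 27 members higher and 1 lower in ProT than HSC, 5 and 4 in DP against ProT and 5 and 4 in DP against HSC. Adjusted over the list alone these counts were 5 and 1, 5 and 5, and 7 and 4. Its camera adjusted p values were 0.586, 0.444 and 0.457. Phf19, a partner of the PRC2 complex, changed by -1.55 ± 0.08 in ProT against HSC and Cbx2 by 0.98 ± 0.18, while Ezh2, the PRC2 methylase, had -0.15 ± 0.10 there and rose by 0.45 ± 0.10 in DP against ProT. Phf1 rose by 1.13 ± 0.09 and Pcgf2 changed by -1.30 ± 0.13 in DP against ProT. Of the H3K4 and H3K27 methylases and demethylases 0 of 18 rose in ProT against HSC, with 0 lower, while in DP 10 were higher and 2 lower than in ProT and 8 higher and 2 lower than in HSC. For this list they were 0 and 0, 10 and 3, and 9 and 3 adjusted over the list alone. Kmt2a changed by 1.05 ± 0.13, Kmt2c by 1.05 ± 0.11, Kdm5a by 0.92 ± 0.12 and the H3K27 demethylase Kdm6b by 0.89 ± 0.13 between ProT and DP. The list's camera adjusted p values were 0.366, 0.146 and 0.0906. Of the DNA methylation and histone deacetylase genes 4 of 21 rose and 1 fell in ProT against HSC, 4 and 4 in DP against ProT, and 7 and 7 in DP against HSC. The counts adjusted over the list alone were 5 and 2, 4 and 4, and 7 and 7, with camera adjusted p values of 0.957, 0.799 and 0.934. In ProT against HSC the median, the mean and the test of the Polycomb and of the DNA methylation list did not share 1 sign. The de novo DNA methylase gene Dnmt3b changed by 0.63 ± 0.14 in ProT against HSC and by -2.52 ± 0.14 in DP against ProT, and Tet1, which oxidises methylcytosine, by 1.69 ± 0.23 at the later step.

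The shape of the path was tested gene by gene as the distance of ProT from the midpoint of HSC and DP, and 4187 genes lay off the midpoint. Of the genes that also differed between HSC and DP, 731 had ProT on the DP side of the midpoint (early) and 2239 on the HSC side (late). These classes do not require ProT to lie between HSC and DP, and they can include genes highest or lowest in ProT. Gzmb, at 5.67 in HSC, 13.54 in ProT and 6.05 in DP, counts as early. How many genes the classes share was not counted. In ProT 831 genes were higher than in HSC and in DP, and 269 were lower than in both. Independent lists of the same sizes would share 283.1 and 199.9 genes. Genes that moved the same way in both steps were also more than independent lists would share, 334 against 227.6 that rose in both and 474 against 248.8 that fell in both, so the excess is not particular to genes highest or lowest in ProT. Both comparisons use the same ProT arrays, and an error in the ProT mean enters the 2 steps with opposite signs. Such error may add to the genes highest or lowest in ProT, but not to those that moved the same way. The 2 comparisons also share 1 estimate of the spread per gene, whose part in the excess was not tested. The highest genes relative to the midpoint were Gzmb (7.67 ± 0.07), Mcpt1 (7.66 ± 0.07), Mcpt2 (6.31 ± 0.08), Mcpt4 (6.30 ± 0.09) and Cyp11a1 (5.85 ± 0.19). The lowest were F13a1 (-5.87 ± 0.11), Ly86, a lymphocyte antigen that pairs with a Toll-like receptor homologue (-4.56 ± 0.43), Ly6a2 (-4.31 ± 0.38), the mitochondrial sulfide oxidase gene Sqor (-4.23 ± 0.08) and the kinase gene Map4k5 (-3.89 ± 0.12). F13a1 stood at 12.19 ± 0.08 in HSC, 6.01 ± 0.24 in ProT and 11.56 ± 0.09 in DP. Leaving out an array moved these counts: without DP replicate 1 or 2 the genes highest in ProT numbered 499 and 494, those lowest in ProT 80 and 91 and those off the midpoint 2138 and 2059. In the same fits the early class held 344 and 336 genes and the late class 1073 and 1020. Without ProT replicate 1 there were 150 genes lowest in ProT, 2373 off the midpoint and 1284 in the late class. Without ProT replicate 2 there were 496 lowest in ProT, and without HSC replicate 1 there were 492 lowest in ProT and 1195 in the early class; the causes were not tested.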

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

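Cyclic loess between the arrays was chosen only after the data had been seen; all other alternatives were set before the data were examined. Of the alternative values of named genes, 2532 kept the direction and the side of the threshold, 42 no longer passed, 16 newly passed and 5 changed direction. For gene lists these numbers were 1304, 44, 34 and 22. Camera with an estimated correlation accounts for most lists that no longer passed, with 1, 1 and 2 lists called in ProT against HSC, DP against ProT and DP against HSC where the preset called 12, 15 and 15. That setting changes the correlation and also leaves the test only 3 degrees of freedom. The parts of these 2 changes in the lost calls were not separated, so the lost calls do not show that correlation between genes removed them. Signal over background was not measured with control probe sets here, and in simulated data 36% of log2 changes of 0.5 were called.

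At an adjusted p below 0.01, by construction fewer genes pass: 891 higher and 644 lower in ProT than HSC, 1645 and 2396 in DP against ProT, 2060 higher in DP than HSC, 486 highest and 85 lowest in ProT, 2001 off the midpoint, 357 early and 994 late. With a change of at least 2-fold required, the counts were 692 and 538, 879 and 1420, 1021 and 1727, 362 and 54, 1155, 250 and 440. Fitting only the 2 populations compared gave 1013 higher and 779 lower in ProT than HSC and 167 lowest in ProT, against 1565, 1375 and 269 in all 6 arrays. For DP against ProT such a fit gave 3282 higher and 4126 lower, against 2899 and 3607. The changes are the same in both fits, so the counts differ through the variance estimate and its degrees of freedom. The median difference between replicates was 0.119 in HSC, 0.1004 in ProT and 0.0799 in DP. In the fit of all 6 arrays, ProT against HSC thus draws on the smaller spread of DP, and DP against ProT on the larger spread of HSC. Median centring gave 4522 genes higher in DP than ProT against 2899, and 473 lowest in ProT against 269; the cause was not tested.

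The deviations of arrays with the same replicate number had correlations of 0.0584 (HSC and ProT), -0.0222 (HSC and DP) and -0.0428 (ProT and DP). These values show no broad shared shift, but they cannot exclude a shared origin that acts on some genes. With the number as a replicate block, 1534 genes were higher and 1311 lower in ProT than HSC, 2722 and 3546 in DP against ProT, and 3060 and 3697 in DP against HSC, with 835 highest and 261 lowest in ProT, 4091 off the midpoint, 714 early and 2167 late.

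When each array was left out in turn, the lone array of that population was assumed to vary like the other populations. The counts then ranged from 1013 to 1988 higher and 779 to 1994 lower in ProT than HSC, 1467 to 3282 higher and 2047 to 4126 lower in DP than ProT, and 1940 to 3188 higher and 2361 to 3862 lower in DP than HSC. Genes highest in ProT ranged from 494 to 1090, lowest 80 to 496, off the midpoint 2059 to 5233, early 336 to 1195 and late 1020 to 2390. The cause of these ranges was not tested.

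All results that changed direction belong to genes that had not passed or lists that camera had not called, and the cause was not tested. Notch1 in DP against ProT was at 0.0732 after quantile normalization, 0.0821 after median centring and 0.0738 after cyclic loess, and ranged from -0.1143 to 0.046 over the left-out arrays. Meis1 in ProT against HSC ranged from -0.0676 to 0.5887. For lists the direction is that of the test, which can differ from the sign of the median log2 change given here. In ProT against HSC it changed for the erythroid list (median 0.0459) with the filter on dim genes, the Polycomb group (0.0146) with fry and the interferon list (-0.0479) with centring. It also changed for the DNA methylation list, at -0.024 with quantile normalization, -0.1417 with centring, -0.0336 with the filter on dim genes and -0.0597 with the mean of all probe sets and with fry. That list changed direction at 0.0279 with fry in DP against ProT, and in DP against HSC at 0.0566 with centring and 0.0224 with fry. Leaving out an array changed the direction of further lists, whose medians in ProT against HSC ranged from -0.1952 to -0.0371 for stem genes, -0.1326 to 0.0913 for erythroid genes and -0.1318 to 0.0189 for DNA methylation. Likewise they ranged from -0.1626 to 0.1139 for ribosome biogenesis, 0.0228 to 0.2648 for glycolysis and -0.0538 to 0.0448 for the interferon list. For DNA methylation they ranged from 0.0208 to 0.0447 in DP against ProT and from -0.0303 to 0.1556 in DP against HSC, and for the BCL2 family from -0.0927 to 0.0461 in DP against ProT.

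Between populations the mean Spearman correlation over all probe sets was 0.971 for HSC and ProT, 0.952 for ProT and DP and 0.945 for HSC and DP, and over the 1000 most variable genes the Pearson correlation was 0.271, 0.241 and -0.114, genes picked for their differences.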

Other observations

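The tests of the gene families and the test of leftover HSC-like cells were chosen only after the result was seen, and all genes named here from families and second lists were picked after their values were seen.

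Genes of cholesterol synthesis fell together in DP: all 14 measured enzymes were lower than in ProT, by a median log2 change of -2.23, and all 14 were lower than in HSC, by -1.81. Hmgcs1, which makes the precursor of mevalonate, changed by -3.05 ± 0.16 from ProT to DP. The aminoacyl-tRNA synthetases, which load amino acids for protein synthesis, fell in 15 of 15 cases with a median of -0.91, Iars among them at -1.09 ± 0.19. After quantile normalization, median centring or cyclic loess 12 to 13 of them fell. Camera adjusted p values from ProT to DP were 8.36e-11 for cholesterol synthesis and 3.36e-07 for the synthetases, and adjusted p = 0.162 for both with an estimated correlation.

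Gimap genes, GTPases of lymphocyte survival, rose as a block already in ProT, 8 of 8 with a median of 2.60 (camera adjusted p = 8.36e-11, and adjusted p = 0.162 with an estimated correlation), and Gimap4 changed by 4.35 ± 0.08. T cell receptor alpha variable segments rose later. In ProT against HSC 1 of 6 passed, and in DP against ProT 6 of 6 with a median of 3.12, such as Trav19 at 2.55 ± 0.13 (camera adjusted p = 3.36e-07, and adjusted p = 0.162 with an estimated correlation). Schlafen genes, which restrain growth in lymphocytes, fell in 4 of 9 cases and rose in 0 from HSC to ProT, by a median of -0.73 (camera adjusted p = 0.00284, and adjusted p = 0.349 with an estimated correlation). From ProT to DP 5 of 9 rose, Slfn1 at 3.51 ± 0.45 (camera adjusted p = 0.0025, and adjusted p = 0.349 with an estimated correlation), and DP against HSC was not called, with 4 higher and 2 lower (camera adjusted p = 0.295). Of the 12 families tested, the other 7 were granzymes, Klr receptors, Ifi200, Rpl and Rps ribosomal proteins, integrins and histones. Camera called granzymes (3 of 10 higher), Klr receptors (8 of 23 higher, 2 lower), Rpl (0 of 34) and Rps genes (0 of 21) in ProT against HSC, with adjusted p = 0.000188, 0.000627, 0.00372 and 0.0188, and adjusted p = 0.162, 0.162, 0.528 and 0.534 with an estimated correlation. In DP against ProT it called granzymes (3 of 10 lower), Ifi200 (3 of 8 higher, 1 lower), Rpl (4 of 34 lower) and Rps genes (2 of 21 lower), with adjusted p = 0.00664, 0.00748, 0.0025 and 0.0315, and adjusted p = 0.171, 0.436, 0.528 and 0.545 with an estimated correlation. After quantile normalization, median centring or cyclic loess 3 to 4 granzymes, 2 to 4 Rpl and 0 to 1 Rps genes were lower and 4 to 5 Ifi200 genes higher in DP than ProT, with 0 to 1 granzyme, Rpl and Rps genes higher and 0 to 1 Ifi200 genes lower; the cause was not tested. In DP against HSC camera called none of the 7, and integrins and histones in no comparison.

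Of the first lists, 13 of 20 stromal and thymic epithelial, 11 of 17 B lineage and 7 of 14 macrophage genes were higher in DP than in ProT, the last list not called by camera, and second lists written before their values were looked at tested where this could come from. A shift of all dim probe sets is argued against, since the median changes of lists of liver, muscle and neuron genes were 0.0132, 0.0468 and 0.0931, while the second thymic epithelial list had 0.306, with 10 of 17 members risen and 0 fallen. RNA of thymic epithelial cells and of macrophages in the DP samples stays open: their second lists lay at percentiles 100 and 99.9 of random lists matched on signal (2 of 17 and 6 of 14 members at or above the median signal already in ProT), with Prss16 at 9.99 in DP (2.59 ± 0.09) and Tbata at 3.24 ± 0.09 for epithelium, and Apoe at 10.15 (1.45 ± 0.11) and Gas6 at 1.41 ± 0.08 for macrophages. The second B cell list lay at percentile 0 (2 of 13 rose, 7 fell, median -0.75), which by the criterion written beforehand counts against B cell RNA. That criterion took no account of genes ProT cells hold at high levels and lose, such as Cxcr5 from 9.70 (-4.40 ± 0.12). The 2 members below the median in ProT, Fcmr and Fcrla, rose (0.70 ± 0.08 and 0.82 ± 0.08). With this reservation, which was not part of the criterion, B cell RNA cannot be told apart from expression by the thymocytes. The second fibroblast and endothelial lists lay at percentiles 86.9 and 28, the labels name no sort that would remove other cells, and regulation in the DP cells themselves, which grew in mice and not in culture, was not tested.

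The 269 genes lower in ProT than in HSC and in DP could come from HSC-like cells left over in the DP samples, which would bring back all genes lost from HSC to ProT by a common share. Of the signal lost by the 92 genes that fell at least 8-fold from HSC to ProT, DP regained a median share of 0.006, with quartiles of -0.0056 and 0.031 and 84 of the 92 below 0.1. Of the 92, the 14 that were higher in DP than ProT regained a median share of 0.118 (7 of the 14 below 0.1), and the 269 genes, most of which fell less and all of which were selected for being higher in DP, 0.999. A common share as small as that of the 92 genes argues against leftover HSC-like cells as the source of genes such as F13a1, at 12.19 in HSC and 11.56 in DP. A change with the culture conditions, which the design does not separate from the stage, was not tested. Nor was RNA of macrophages or other myeloid cells in the DP samples tested as a source of these genes.

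Several mast cell and NK genes, such as Mcpt4 and Gzmb, had their highest signal in ProT, though the first mast cell list was not called by camera against HSC, and second lists written beforehand tested whether mature cells of those types in the culture could account for it. Of the second mast cell list 58.3% rose in ProT against HSC (7 of 12, with 1 fallen), among them Alox5 at 10.99 (3.40 ± 0.39), while Mrgprb1, a receptor of connective tissue mast cells, had a mean of 4.56. Of the second NK list 45.5% rose (5 of 11, with 0 fallen), with Il12rb2 at 11.91 (3.49 ± 0.12), whereas Klra3 was at 4.80. In ProT 6 of 12 and 4 of 11 members were at or above the median signal, and 3 and 2 further members were left out since the first lists hold them. Mature mast or NK cells in the culture cannot be told apart from expression of these genes by ProT cells, since in each list some members rose and others did not.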
